A study of Mus musculus with 6 samples.

How the data were processed

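Gene expression was measured by RNA sequencing in bone marrow-derived macrophages from wild-type mice aged 6 to 8 weeks. Per the labels' protocols, marrow cells were differentiated with M-CSF at 20 ng/mL for 7 days and treated for 24 h with IL-4 at 20 ng/mL, alone or with CGRP. The CGRP concentration is not printed because the labels can be read in more than one way. Per the labels' protocols, total RNA was extracted with TRIzol, RNA with a quality number of at least 6.5 was used, and libraries were prepared from 1 µg with a stranded mRNA kit. There were 2 groups of 3 libraries, named by the treatment and replicate number in the labels.

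The deposited table holds estimated counts for 57180 genes in 6 library columns, and the authors' mean of each group, which was used only to check the columns. Per the submitters' processing notes, fastp, HISAT2 and StringTie were used with mouse genome build GRCm39. Versions, the annotation, the counting step and whether it used strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Between 23.3% and 26.6% of values above 0 in a library were not whole numbers (tolerance 1e-06), so the deposited values are estimated (expected) counts, which were rounded to whole numbers before testing. The table has 525 genes without a name, kept under their identifiers, and 0 unassigned columns of per-sample values. Gene names and annotation terms come from the table. No coordinates are printed because the reference genome used here was of another build.

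Totals ranged from 20088895 to 24060444 counts per library. Genes were filtered with filterByExpr by group, which kept 13260 genes holding 99.91% of counts. Libraries were scaled with TMM factors (0.985 to 1.016), and IL-4+CGRP was compared with IL-4 by the edgeR 4.0.16 quasi-likelihood F test (robust, two-sided, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common biological coefficient of variation was 8.6%. CPM values are counts divided by TMM-scaled totals, and SEs are the log2 fold change divided by the square root of the F statistic. A change of at least 2-fold was counted separately.

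Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. There were 36 lists for macrophage biology and 13 for other cell types and RNA quality, of which 48 had at least 5 tested members. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided, adjusted over the lists), and again with a correlation estimated for each list, where 0 lists passed. At an unadjusted p under 0.05 with an estimated correlation, 13 lists passed. By fry, 25 lists passed for a shift on balance one way and 41 for change in either direction, neither of which compares a list with other genes. Genes named are the 10 highest and 10 lowest log2 fold changes among called genes with an average log2 CPM of at least 1, groups that do not overlap and a symbol that is not a clone name; 14 genes of interest whatever their result; and up to 4 members per list with the smallest p past the threshold, or 2 where none passed. Of the genes this rule names, some are not reported here. Annotation terms with 10 to 500 tested members were tested by a one-sided Fisher's exact test against all tested genes that carry an annotation (12747 for GO, 5337 for KEGG), using scipy 1.17.1 and statsmodels 0.14.6 in Python 3.11.15.

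Libraries correlated at 0.982 to 0.993 (Pearson, log2 CPM across genes, which are not independent replicates). IL-4+CGRP replicate 2 correlated at 0.9882 with IL-4 replicate 1, and at 0.9876 and 0.9869 with replicates 1 and 3 of its own group. On the first principal component (37.6% of variance) it lay at -0.17, against 21.98 and 27.05 for IL-4+CGRP replicates 1 and 3. The IL-4 libraries lay from -25.97 to -11.22. Every pair within a group differed by more than counting noise (chi-square per degree of freedom of 2.98 to 20.2), so no library was treated as a repeat of another. Near-identical copies of mitochondrial transcripts were found with BLAST+ 2.17.0 among GENCODE transcripts, with at least 95% identity.

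Alternatives were other scalings (DESeq2 size factors, upper quartile factors, library totals alone), no count filter or a mean count of at least 50, DESeq2 1.42.0, limma-voom, a dispersion fit that was not robust, the replicate number as a block, and leaving out each library in turn. The fits without a correlated pair of libraries, without mitochondrial and ribosomal RNA genes, and with the gene length trend of each library removed were added after seeing the data. The scripts were tested on simulated data for this comparison with 200 of 13260 genes changed: 32% of genes changed 1.3-fold were recovered, 54% at 1.5-fold, 80% at 2-fold and 100% at 4-fold, and 0.09% of unchanged genes were called. A planted list of 30 genes shifted by 0.3 (log2) was recovered while 0 of 40 random lists were called by camera, and of 501 simulated terms the planted one was recovered and 0 others were called. Simulated genes were drawn independently of each other. The simulation therefore cannot show how often lists of correlated genes are called wrongly.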

Results

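RNA was sequenced from wild-type mouse bone marrow-derived macrophages, which are marrow cells grown into macrophages with M-CSF. The series title concerns sensory nerves that induce macrophages with high IL-4 receptor alpha in kidney ischaemia and reperfusion. One group of cultures received IL-4, a cytokine that drives alternative activation, and the other received IL-4 together with CGRP, a neuropeptide released by sensory nerves. There were 3 libraries in each group. Total counts were 20088895, 21536259 and 24060444 in IL-4 replicates 1 to 3, and 23869303, 21768588 and 21984645 in IL-4+CGRP replicates 1 to 3. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

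The comparison asks how macrophages given IL-4 and CGRP differ from those given IL-4 alone. No group without IL-4 was sequenced, so the response to IL-4 itself was not measured. An effect of CGRP that does not depend on IL-4 cannot be told apart from a changed response to IL-4. Thbs1 (thrombospondin 1, a matrix glycoprotein) rose from 75.9 ± 5.48 to 326 ± 21.8 CPM (counts scaled to library size; SD, n = 3 in each group). That is 4.29-fold, a log2 fold change of 2.10 ± 0.07 (SE), with an edgeR adjusted p = 2.8e-08. Inhba (the activin A subunit) rose 4.59-fold, Itga1 (integrin alpha 1) 6.29-fold, Nrg1 (neuregulin 1) 3.98-fold and Ptgs2 (cyclooxygenase 2) 3.84-fold. Itgax (CD11c) fell from 149 ± 3.91 to 62.9 ± 5.35 CPM (SD, n = 3), 2.37-fold lower with an edgeR adjusted p = 1.3e-06. Ocstamp and Dcstamp, membrane proteins needed for fusion of osteoclasts and macrophages, fell 3.49-fold and 2.37-fold.

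Among 13260 genes tested, 307 were higher and 204 lower in IL-4+CGRP, 56 and 21 of them by at least 2-fold. Apart from mt-Co2, at 0 counts in every IL-4 library and with an uncertain level, the other strongest increases with an average log2 CPM of at least 1 were in Arg2 (arginase 2, 2.96-fold), Scn3a (2.87-fold), Pmepa1 (2.78-fold) and Clec4n (Dectin-2, 2.59-fold). The other strongest decreases were in Siglecf (3.34-fold), Ccr9 (2.66-fold), Cdkn1c (2.45-fold), Nes (2.19-fold), Clec4b1 (2.08-fold), Map2 (2.06-fold) and Gbp2b (2.03-fold). Their edgeR adjusted p-values ran from 1.2e-04 for Clec4n to 0.0077 for Clec4b1. All 511 called genes had groups that did not overlap, against 21% of all tested genes and 10% by chance. With 3 libraries a group a call nearly requires this, so it is not separate support. The median absolute log2 fold change of the called genes was 0.40. Of the calls, 60.1% were higher, and 71.2% when libraries were scaled by their totals alone. Without IL-4+CGRP replicate 2, 915 genes were higher and 950 lower. Without any one of IL-4 replicates 1, 2 and 3 or IL-4+CGRP replicates 1 and 3, the counts fell to between 140 and 194 higher and between 80 and 119 lower, and the Clec4b1 call ended without IL-4 replicate 2.

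**Figure D1:**
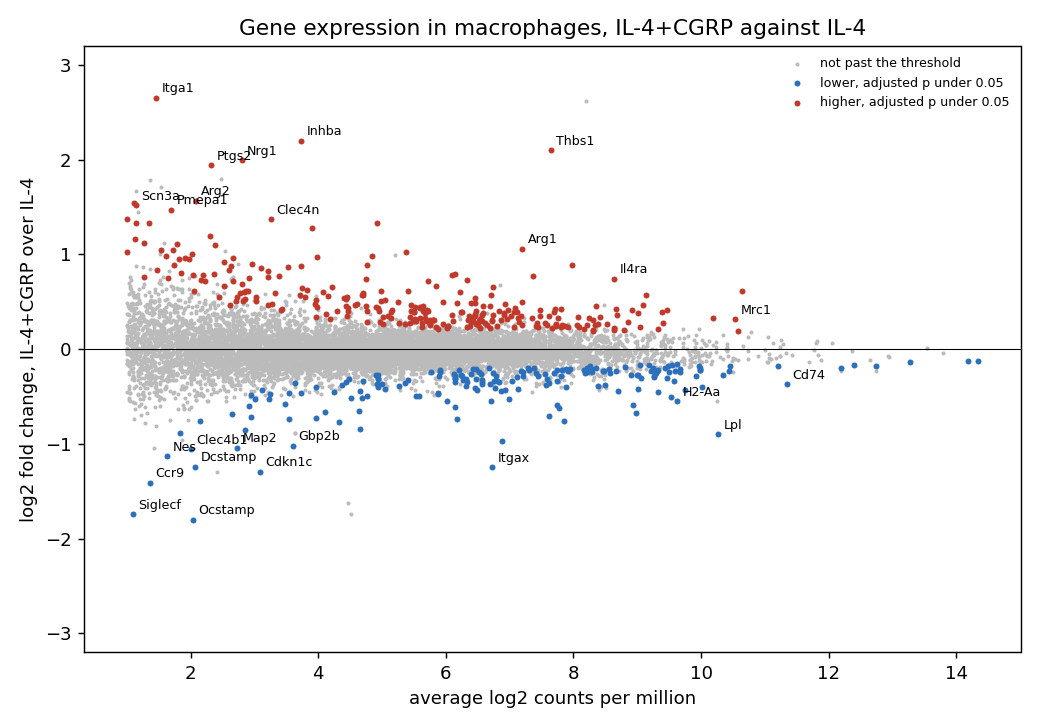
Log2 fold change of IL-4+CGRP over IL-4 (vertical axis) against average log2 CPM (horizontal axis) for genes averaging at least 1, with called genes in red (higher) and blue (lower). Thbs1 at 2.10 and Itgax at -1.25 (log2) stand out at their expression levels; 5 genes outside the axis and genes at 0 counts in a whole group are not drawn.

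Il4ra (ENSMUSG00000030748), the IL-4 receptor alpha chain, rose from 299 ± 14.1 to 499.5 ± 2.35 CPM (SD, n = 3), 1.67-fold with an edgeR adjusted p = 5.4e-06. In the IL-4 receptor and STAT6 pathway list, 6 of 16 tested members rose and 0 fell, also 6 and 0 when adjusted over the list alone. They included the feedback inhibitors Socs3 (2.14-fold, adjusted p = 0.0033) and Cish (1.45-fold, adjusted p = 0.0031). The list was higher by camera (adjusted p = 6.2e-04), but not with an estimated correlation (adjusted p = 0.17 with an estimated correlation). Stat6, the transcription factor of this pathway, had a log2 fold change of -0.06 ± 0.05 (SE) and an edgeR adjusted p = 0.66.

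Members of the IL-4 induced alternative activation list moved in both directions. Arg1 (arginase 1) rose 2.08-fold from 95.02 ± 3.92 to 198 ± 12.6 CPM (SD, n = 3; edgeR adjusted p = 2.7e-06). The lectins Mgl2 (1.68-fold), Clec10a (1.59-fold) and Mrc1 (the mannose receptor, 1.24-fold) also rose, while Clec7a (Dectin-1) fell 1.32-fold. Of 35 tested members, 8 rose, 7 fell and 20 did not pass; adjusted over the list alone, 10 rose and 12 fell. The list had a camera adjusted p = 0.62, with a median log2 fold change of 0.06 and a mean of -0.01; the median was 0.113 without IL-4+CGRP replicate 2, 0.04 without IL-4+CGRP replicate 3 and 0.096 with a mean count of at least 50. Retnla measured 10.4 ± 3.35 and 10.7 ± 3.41 CPM (SD, n = 3), and Chil3 77.5 ± 5.6 and 83.8 ± 8.42 CPM (SD, n = 3), with edgeR adjusted p = 0.97 and adjusted p = 0.54.

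**Figure D2:**
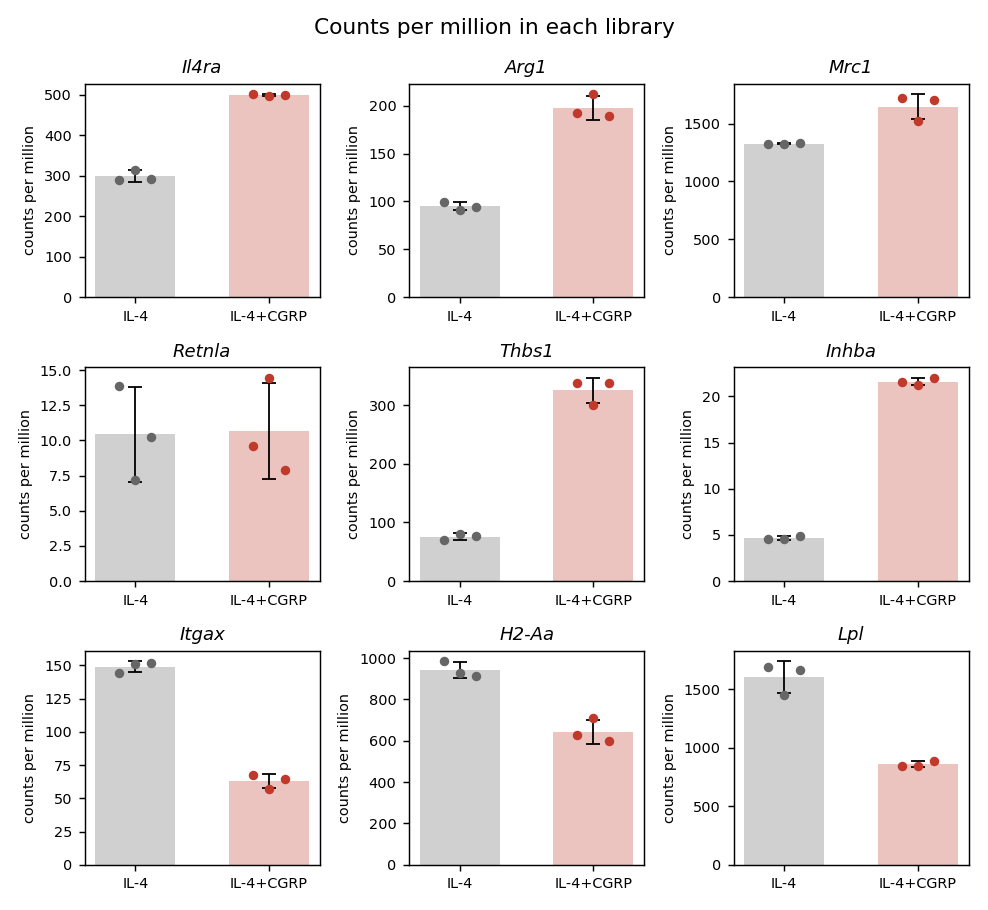
CPM values (vertical axis, starting at 0) in the 3 libraries of each group for 9 genes; bars are means, error bars are SD and points are libraries. Il4ra, Arg1, Mrc1, Thbs1 and Inhba lie higher and Itgax, H2-Aa and Lpl lower in every IL-4+CGRP library than in every IL-4 library, while the groups overlap for Retnla.

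Among CGRP receptor and adenylyl cyclase signalling genes, Ramp3, an accessory protein of calcitonin-family receptors, rose 2.52-fold from 1.20 ± 0.235 to 3.01 ± 0.497 CPM (SD, n = 3; edgeR adjusted p = 0.0072). The adenylyl cyclases Adcy6 (1.42-fold) and Adcy3 (1.18-fold) rose, and Gnas, which encodes the stimulatory G protein alpha subunit, fell 1.24-fold (edgeR adjusted p = 0.0017). The CGRP receptor genes Calcrl (log2 fold change -0.19 ± 0.09, SE; adjusted p = 0.32) and Ramp1 (-0.77 ± 0.23, SE; adjusted p = 0.095) did not pass the edgeR test. In this list 4 of 20 tested members rose and 1 fell, or 4 and 2 when adjusted over the list alone, with a camera adjusted p = 0.61. The Ramp3 call ended without IL-4 replicate 2 or 3. The Adcy3 and Adcy6 calls ended under DESeq2 and without IL-4 replicate 2 or 3 or IL-4+CGRP replicate 1 or 3, and the Adcy3 call also without IL-4 replicate 1.

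Genes induced by cAMP and CREB included Thbs1, Vegfa (1.86-fold, adjusted p = 1.2e-04) and Pde4b (a cAMP phosphodiesterase, 1.57-fold, adjusted p = 0.0022) among those that rose, and Rgs2, a G protein signalling regulator that fell 1.46-fold. Of 31 tested members, 5 rose and 1 fell, or 7 and 2 adjusted over the list alone. The list was higher by camera (adjusted p = 0.0042; adjusted p = 0.15 with an estimated correlation). In the list of neuropeptide and other G protein-coupled receptors, 3 of 26 tested members rose and 0 fell, or 7 and 0 adjusted over the list alone. They were Hcar2 (the niacin receptor, 1.85-fold), Gpr35 (1.32-fold) and P2ry13 (1.25-fold), and the camera adjusted p = 3.4e-04 (adjusted p = 0.15 with an estimated correlation). All 3 calls ended without IL-4 replicate 1 or 3. They also ended without IL-4 replicate 2 for Hcar2 and P2ry13, without IL-4+CGRP replicate 1 for Gpr35 and P2ry13, without IL-4+CGRP replicate 3 for Hcar2 and P2ry13, and under DESeq2 or a dispersion fit that was not robust for P2ry13.

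Inflammatory cytokines and enzymes were higher as a list, with 5 of 24 tested members up and 0 down, or 7 and 0 adjusted over the list alone (camera adjusted p = 4.1e-04; adjusted p = 0.15 with an estimated correlation). Ptgs2 rose from 2.01 ± 0.171 to 7.71 ± 0.438 CPM (SD, n = 3; edgeR adjusted p = 1.4e-05). Il1b rose 2.58-fold from 1.07 ± 0.134 to 2.75 ± 0.743 CPM (SD, n = 3; edgeR adjusted p = 0.012), and the costimulatory ligands Cd86 and Cd80 rose 1.37-fold and 1.52-fold. Tnf (log2 fold change -0.08 ± 0.10, SE; adjusted p = 0.73), Nos2 (0.20 ± 0.24, SE; adjusted p = 0.73) and Il10 (-0.04 ± 0.13, SE; adjusted p = 0.90) did not pass the edgeR test. Il6 had 0, 5 and 4 counts in the IL-4 libraries and 4, 7 and 4 in the IL-4+CGRP libraries, too few to be tested. The Il1b call ended without IL-4 replicate 2 or 3 or IL-4+CGRP replicate 1, and the Cd80 call in every leave-one-out fit except that without IL-4+CGRP replicate 2.

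Anti-inflammatory mediators moved both ways: Il1rn, the interleukin-1 receptor antagonist, rose 1.58-fold (edgeR adjusted p = 2.5e-05), whereas Anxa1 (annexin A1) fell 1.60-fold (edgeR adjusted p = 5.4e-06) and Atf3 fell 1.34-fold. Of 27 tested members, 4 rose and 3 fell, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.76). Among chemokines, Ccl24 (eotaxin-2) rose 2.00-fold and Ccl9 fell 1.3-fold. Cxcl3 had 1, 4 and 1 counts in the IL-4 libraries against 19, 10 and 17, and Cxcl2 had 11, 4 and 11 against 27, 23 and 29; both were called higher. That made 3 of 22 tested chemokines up and 1 down, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.61). With the gene length trend removed the list passed as higher (adjusted p = 0.039, in a range of 0.039 to 0.99 over its alternatives with a preset correlation). The Ccl9 call ended without IL-4 replicate 1, 2 or 3 or IL-4+CGRP replicate 1, the Cxcl3 call without IL-4 replicate 1 or 3 or IL-4+CGRP replicate 1 or 3, and the Cxcl2 call in every leave-one-out fit except that without IL-4+CGRP replicate 2. The Cxcl2 call also ended under DESeq2, limma-voom and a dispersion fit that was not robust, and the Ccl9 call with the length trend removed.

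Itgb7 (integrin beta 7) rose 1.73-fold (edgeR adjusted p = 5.4e-06), Ccr1 1.51-fold, Itgam (CD11b) 1.33-fold and Ccr7 1.38-fold. In the list of chemokine receptors and migration genes 6 of 26 tested members rose and 2 fell, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.11). NF-kB pathway components and feedback targets had 2 of 25 members up, Tnfaip2 (1.20-fold) and Ier3 (1.21-fold), and 0 down, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.087). Of 39 interferon response genes 4 rose, led by the guanylate-binding proteins Gbp5 (1.32-fold) and Gbp7 (1.27-fold), and 3 fell, Ifit2 and Ifit3 among them. Adjusted over the list alone 4 rose and 4 fell (camera adjusted p = 0.58). Another guanylate-binding protein, Gbp2b, which is outside the list, was 2.03-fold lower. The Ifit2 and Ifit3 calls ended in every leave-one-out fit except that without IL-4+CGRP replicate 2. Library totals alone and DESeq2 also ended the Ifit2 call. The Ccr7 and Gbp7 calls ended without IL-4 replicate 2, the Tnfaip2 call without IL-4 replicate 2 or 3, and the Ier3 call without IL-4 replicate 1, 2 or 3 or IL-4+CGRP replicate 1.

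Growth factors and repair mediators were higher as a list by camera (adjusted p = 0.0011; adjusted p = 0.15 with an estimated correlation). Of 21 tested members 6 rose, among them Inhba (4.69 ± 0.2 to 21.6 ± 0.411 CPM; SD, n = 3), Nrg1 (2.72 ± 0.566 to 10.9 ± 0.890 CPM; SD, n = 3), Vegfa and Bmp2 (1.48-fold), and 0 fell, also 6 and 0 adjusted over the list alone. Extracellular matrix genes and proteases had 8 of 33 tested members up and 2 down, or 11 and 4 adjusted over the list alone (camera adjusted p = 1.7e-05; adjusted p = 0.15 with an estimated correlation). Besides Thbs1, the collagenase Mmp8 rose 2.52-fold (edgeR adjusted p = 5.4e-06) and the membrane protease Mmp14 1.3-fold, while macrophage elastase, Mmp12, fell 1.34-fold (edgeR adjusted p = 5.9e-04). The Bmp2 call ended without IL-4 replicate 2 or 3 or IL-4+CGRP replicate 1.

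The list of antigen presentation by MHC class II was lower by camera (adjusted p = 1.7e-05; adjusted p = 0.17 with an estimated correlation). Of 15 tested members 8 fell, and 2 rose, the costimulatory ligands Cd80 and Cd86; adjusted over the list alone 9 fell and 2 rose. H2-Aa fell from 942 ± 36.6 to 644 ± 57.8 CPM (SD, n = 3; edgeR adjusted p = 5.1e-04), H2-Eb1 fell 1.5-fold, H2-DMb1 1.47-fold and Cd74, the invariant chain, 1.29-fold. The Cd80 call ended in every leave-one-out fit except that without IL-4+CGRP replicate 2. Of 17 listed MHC class I genes 0 passed the edgeR test, also 0 adjusted over the list alone (camera adjusted p = 0.62). At an unadjusted p under 0.05, 4 passed, and DESeq2 and limma-voom called 0. In this list Nlrc5 and H2-Q6 had the smallest p-values, with log2 fold changes of 0.15 and 0.13. H2-M2, a class I gene outside the list, was called lower. Without IL-4+CGRP replicate 2, 8 class I genes passed as lower (H2-D1, H2-K1 and B2m among them) and Nlrc5 as higher, and the class I list passed as lower (adjusted p = 0.049, in a range of 0.049 to 0.98 over its alternatives with a preset correlation). Without both this library and IL-4 replicate 1 the same 8 genes passed as lower and Nlrc5, H2-Q6 and H2-Q4 as higher. B2m also passed as lower with no count filter and with the gene length trend removed, where H2-Q6 passed as higher.

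Among 15 tested dendritic cell markers, Itgax and Siglech (3.13-fold lower) fell and Ccr7 rose, or 6 down and 1 up adjusted over the list alone, with a median log2 fold change of -0.10 (camera adjusted p = 0.03; adjusted p = 0.23 with an estimated correlation). The list's call ended without IL-4 replicate 2 or 3 or IL-4+CGRP replicate 1, and so did the Siglech call; the Ccr7 call ended without IL-4 replicate 2. The list's median moved to -0.23 without IL-4 replicate 1 and -0.25 without IL-4+CGRP replicate 2, to -0.27 without both of these libraries, and to -0.22 with a mean count of at least 50.

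Among genes of fatty acid uptake and oxidation, Lpl (lipoprotein lipase) fell from 1604 ± 135 to 860.2 ± 23.9 CPM (SD, n = 3), 1.86-fold with an edgeR adjusted p = 7.3e-06. Lipa (lysosomal acid lipase) fell 1.34-fold and the fatty acid transporter Cd36 1.22-fold. In the fatty acid uptake and oxidation list 5 of 31 tested members fell and 1 rose, or 9 and 1 adjusted over the list alone (camera adjusted p = 3.6e-04; adjusted p = 0.15 with an estimated correlation). Lipid-associated macrophage and osteoclast-related genes had 7 of 22 tested members down, Ocstamp, Dcstamp, Lpl and Mmp12 among them, and 1 up, Clec4n, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.21 with an estimated correlation). Lysosome and autophagy genes had 7 of 39 members down and 1 up, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.0039; adjusted p = 0.23 with an estimated correlation). Ctsl (cathepsin L) rose 1.53-fold, a call that ended when the gene length trend was removed.

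Among receptors for dying cells and scavenger receptors Cd5l, a secreted scavenger protein, fell 1.63-fold, and Stab1 (1.33-fold), Cd300lf (1.3-fold) and Gas6 (a bridging ligand of the TAM receptors, 1.27-fold) rose. In that list 3 of 30 tested members rose and 3 fell, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.90). Mertk measured 194 ± 19.0 and 209.5 ± 11.6 CPM (SD, n = 3; edgeR adjusted p = 0.52). The Fc receptors Fcgr3 and Fcgr2b rose 1.31-fold and 1.26-fold, and the complement regulator Cfp (properdin) 1.34-fold. Fc and complement receptors had 5 of 18 tested members up and 2 down, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.15).

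Chaperones and other genes of the integrated stress response and unfolded protein response were lower: 6 of 27 tested members fell and 1 rose, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0069; adjusted p = 0.15 with an estimated correlation). Calr (calreticulin) fell 1.26-fold, Atf3 1.34-fold and the endoplasmic reticulum chaperones Hsp90b1 and Hspa5 1.21-fold and 1.19-fold. The heat shock list, a sign of cell handling, moved with them, with 3 of 18 tested members down (Hspa8, Hsp90aa1 and Hsp90ab1) and 1 up (Ier3), or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0039; adjusted p = 0.15 with an estimated correlation). NRF2 antioxidant response genes had 2 of 25 members down, Gpx1 (glutathione peroxidase 1, 1.31-fold) and Tkt (1.16-fold), and 2 up, Slc7a11 (1.78-fold) and Slc40a1 (1.20-fold), or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0048; adjusted p = 0.23 with an estimated correlation). Apart from Calr, Atf3 and Gpx1, each of these calls ended in at least 1 leave-one-out fit: without IL-4 replicate 3 for Hsp90b1, IL-4 replicate 2 or 3 for Hspa5, IL-4 replicate 2 for Hspa8, and IL-4 replicate 1, 2 or 3 or IL-4+CGRP replicate 1 for Ier3. Without IL-4 replicate 1 or 3 or IL-4+CGRP replicate 1 or 3 the Hsp90aa1 call ended, without IL-4 replicate 2 or 3 or IL-4+CGRP replicate 3 the Slc7a11 call, and in every leave-one-out fit except that without IL-4+CGRP replicate 2 the Tkt, Slc40a1 and Hsp90ab1 calls. Under library totals alone the Tkt and Hsp90ab1 calls ended, under DESeq2 the Hsp90ab1 and Slc40a1 calls, and under limma-voom or a dispersion fit that was not robust the Slc40a1 call.

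Ribosomal protein and mitochondrial metabolism genes lay slightly lower as lists. Cytoplasmic ribosomal protein genes had a median log2 fold change of -0.25, with 2 of 42 members down, Rps6 and Rpsa, and 0 up, also 2 and 0 adjusted over the list alone (camera adjusted p = 8.0e-07; adjusted p = 0.52 with an estimated correlation). All genes with a ribosomal protein symbol, not only those listed, held 1.85%, 1.51% and 1.52% of counts in IL-4 replicates 1 to 3. In IL-4+CGRP replicates 1 to 3 this share was 1.26%, 1.71% and 1.22%. The list median of -0.25 covers the 42 listed genes alone. Nuclear genes of oxidative phosphorylation had 0 of 41 members past the edgeR test, also 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma-voom, and a median log2 fold change of -0.16 (camera adjusted p = 1.7e-04; adjusted p = 0.56 with an estimated correlation); Atp5f1b and Ndufv2 had values of -0.17 and -0.24, and passed without IL-4+CGRP replicate 2, without both this library and IL-4 replicate 1, and with no count filter, as did Atp5f1b with the gene length trend removed. The tricarboxylic acid cycle list had 1 of 25 members down, Mdh1 (1.26-fold), and 0 up, also 1 and 0 adjusted over the list alone (camera adjusted p = 0.006; adjusted p = 0.17 with an estimated correlation). The Rps6 and Rpsa calls ended without IL-4 replicate 2 or 3 or IL-4+CGRP replicate 1 or 3, the Rpsa call also without IL-4 replicate 1, and the Rps6 call when the gene length trend was removed. The ribosomal median moved to -0.13 without IL-4 replicate 1, -0.15 without IL-4+CGRP replicate 3 and -0.46 without IL-4+CGRP replicate 2. The oxidative phosphorylation median moved to -0.07 without IL-4 replicate 1, -0.09 and -0.08 without IL-4+CGRP replicates 1 and 3, and -0.31 without IL-4+CGRP replicate 2.

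Cell cycle genes of S phase had a median log2 fold change of -0.15, with 1 of 34 members down, Pcna (1.22-fold), and 0 up, or 2 and 0 adjusted over the list alone (camera adjusted p = 2.3e-04; adjusted p = 0.17 with an estimated correlation). Genes of mitosis had 1 of 33 members down, the kinesin Kif11 (1.40-fold), and 0 up, also 1 and 0 adjusted over the list alone (camera adjusted p = 0.0069; adjusted p = 0.15 with an estimated correlation). The p53 and apoptosis list had 1 of 26 members down, Casp1 (1.36-fold), and 0 up, also 1 and 0 adjusted over the list alone (camera adjusted p = 0.19). The mitosis list's call ended without IL-4+CGRP replicate 2 (adjusted p = 0.054, in a range of 0.0019 to 0.054 over its alternatives with a preset correlation), the Pcna call without IL-4 replicate 1 or 3, and the Kif11 call without IL-4 replicate 1, 2 or 3 or IL-4+CGRP replicate 1. The Kif11 call also ended under library totals alone, DESeq2, limma-voom and a dispersion fit that was not robust.

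Arg1, Arg2 and the cystine transporter Slc7a11 were the 3 members that rose among 23 arginine, polyamine and amino acid transport genes, and 0 fell; adjusted over the list alone 7 rose and 4 fell (camera adjusted p = 0.44). Of 20 core macrophage identity genes 4 rose, including Cd14 (1.53-fold) and Itgam, and 0 fell, also 4 and 0 adjusted over the list alone (camera adjusted p = 0.30). Monocyte markers had 3 of 18 members up, Thbs1, Vcan (versican, 2.51-fold) and F10 (1.23-fold), and 1 down, Ccr2 (1.3-fold), or 5 and 1 adjusted over the list alone (camera adjusted p = 0.045; adjusted p = 0.31 with an estimated correlation). Tissue-resident macrophage markers had 3 of 22 members up and 2 down, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.90), with Mrc1 and Gas6 higher and Id3 1.66-fold lower. The monocyte list's call ended in the leave-one-out fits without IL-4 replicate 2 or 3 or IL-4+CGRP replicate 1 or 2, and without both IL-4 replicate 1 and IL-4+CGRP replicate 2, the F10 call without IL-4 replicate 1, the Id3 call without IL-4 replicate 1 or 2 or IL-4+CGRP replicate 1, and the Ccr2 call without IL-4 replicate 1, 2 or 3 or IL-4+CGRP replicate 1.

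The other metabolic and signalling lists did not pass the camera test. Hypoxia response genes had 3 of 22 members up, among them Vegfa, and 2 down, also 3 and 2 adjusted over the list alone (adjusted p = 0.44). Glycolysis genes had 1 of 24 up and 1 down, Pfkp (1.22-fold lower), or 4 and 4 adjusted over the list alone (adjusted p = 0.44). Cholesterol and fatty acid synthesis genes had 1 of 29 up and 0 down, also 1 and 0 adjusted over the list alone (adjusted p = 0.11). Cholesterol efflux genes and LXR targets had 0 of 18 up and 1 down, the LXR alpha gene Nr1h3 (1.26-fold lower), or 2 and 2 adjusted over the list alone (adjusted p = 0.77). Notch, Wnt and TGF-beta genes had 2 of 26 up, Notch1 (1.31-fold) and Notch2 (1.23-fold), and 2 down, Id2 (1.29-fold) and Id3, or 4 and 4 adjusted over the list alone (adjusted p = 0.90). The Pfkp call ended without IL-4 replicate 2 or 3, the Notch1 and Id2 calls without IL-4 replicate 1 or 2 or IL-4+CGRP replicate 1, and the Notch2 and Nr1h3 calls in every leave-one-out fit except that without IL-4+CGRP replicate 2. The Nr1h3 call also ended with a dispersion fit that was not robust.

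**Figure D3:**
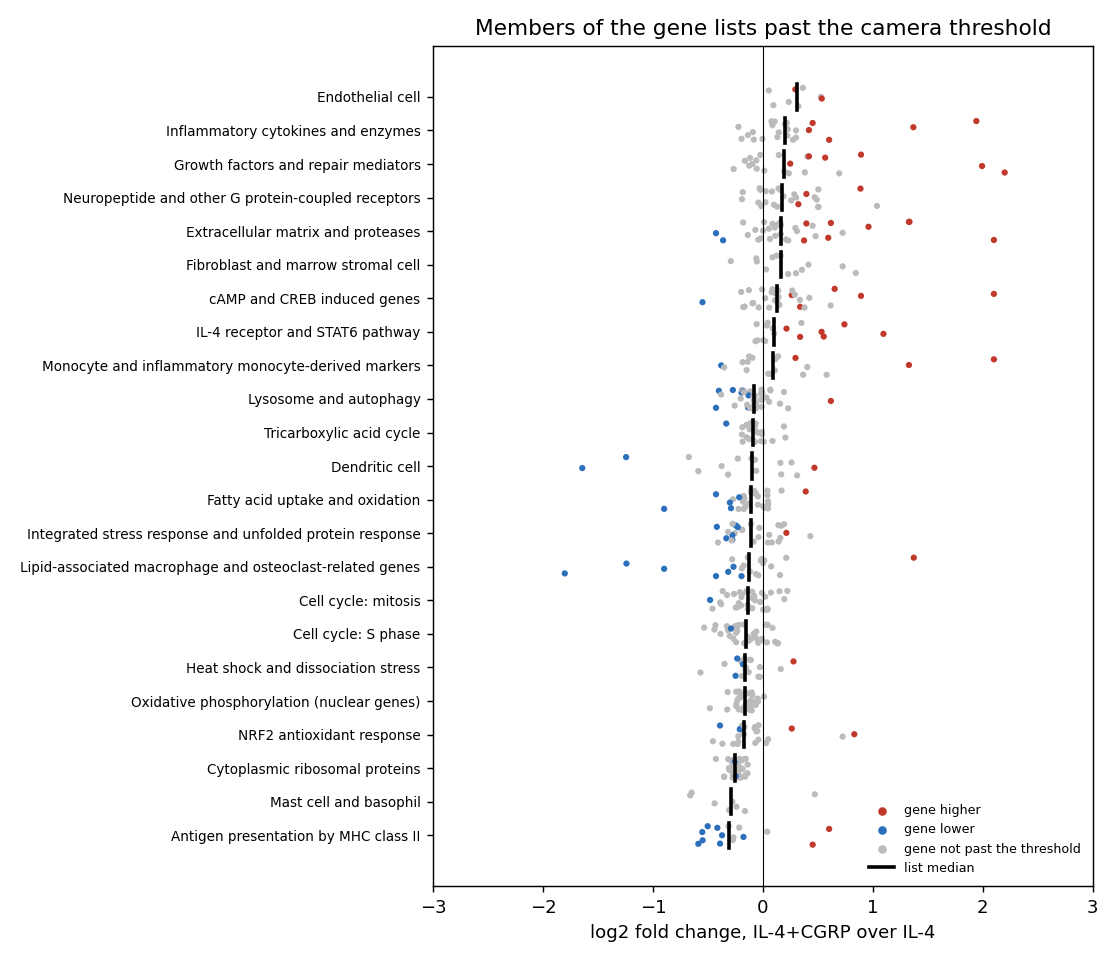
Log2 fold change of IL-4+CGRP over IL-4 (horizontal axis) for each tested member (points) of the 23 lists past the camera threshold, with list medians as black bars. Called genes are red (higher) or blue (lower), the MHC class II median is -0.31, and mast cell, fibroblast and oxidative phosphorylation lists hold no called gene.

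Markers of other cell types were measured in the same libraries. Endothelial markers had 2 of 8 tested members up, Pecam1 (1.45-fold), which macrophages also express, and Kdr (1.23-fold), and 0 down, also 2 and 0 adjusted over the list alone (camera adjusted p = 0.0087; adjusted p = 0.33 with an estimated correlation). Fibroblast and stromal markers had 0 of 13 called by edgeR, DESeq2 and limma-voom, also 0 adjusted over the list alone and 3 at an unadjusted p under 0.05, with log2 fold changes of 0.72 for Col3a1 and 0.23 for Col1a1 (camera adjusted p = 0.049; adjusted p = 0.28 with an estimated correlation). Mast cell and basophil markers had 0 of 8 called by the same tools, also 0 adjusted over the list alone and 2 at an unadjusted p under 0.05, with values of -0.31 for Prss34 and -0.44 for Kit (camera adjusted p = 0.026; adjusted p = 0.20 with an estimated correlation). Eosinophil markers had 0 of 5 up and 1 down, Siglecf, or 0 and 3 adjusted over the list alone (camera adjusted p = 0.06), and neutrophil markers 1 of 11 up, Mmp8, and 0 down, also 1 and 0 adjusted over the list alone (camera adjusted p = 0.54). T and NK cell (0 of 15 called; camera adjusted p = 0.30), B and plasma cell (0 of 13; adjusted p = 0.29) and erythroid and megakaryocyte markers (0 of 8; adjusted p = 0.19) did not pass; adjusted over the list alone 0, 1 and 1 were up and 0 down. At an unadjusted p under 0.05 their edgeR counts were 1, 2 and 1, and DESeq2 and limma-voom called 0, 0 and 1. Cd4 had a log2 fold change of 0.12, Cd22 of 0.20 and Pf4 of 0.99; of adipocyte and osteoblast markers only Runx2 (-0.16) was tested, too few for a list test. Cd22, Pf4 and Col3a1 passed without IL-4+CGRP replicate 2 and without both this library and IL-4 replicate 1. Cd22 and Col3a1 also passed with no count filter, Cd22 and Pf4 under library totals alone and with the gene length trend removed, and Pf4 with a mean count of at least 50, DESeq2, limma-voom and a dispersion fit that was not robust. The endothelial call ended without IL-4+CGRP replicate 1, the fibroblast call without IL-4 replicate 1 or 2 or IL-4+CGRP replicate 1 or 2, and the mast cell call without IL-4 replicate 2 or IL-4+CGRP replicate 2 or 3; the eosinophil list passed without IL-4 replicate 3 or IL-4+CGRP replicate 1. The fibroblast and mast cell calls also ended without both IL-4 replicate 1 and IL-4+CGRP replicate 2, and the fibroblast call with the length trend removed. The Kdr call ended in every leave-one-out fit except that without IL-4+CGRP replicate 2, and under DESeq2, limma-voom and a dispersion fit that was not robust.

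Mitochondrially encoded mt-Co2 (ENSMUSG00000064354) had 0 counts in every IL-4 library and 180, 186 and 181 in the IL-4+CGRP libraries, at least 57.7-fold higher against a floor of 3 counts per library. A near-identical nuclear copy, Gm28661, held 8946, 7630 and 8838 counts in the IL-4 libraries and 6641, 7636 and 6044 in the IL-4+CGRP libraries, so the level of mt-Co2 is uncertain, as are those of mt-Co1 and other mitochondrial genes with copies. The 12 tested mitochondrial transcripts had mt-Co2 up and mt-Co1 down (log2 fold change -0.17), or 1 and 4 adjusted over the list alone. Their median was -0.25, also with mt-Co2 at its bound, but their mean was 0.31 with mt-Co2 at its fitted value (camera adjusted p = 0.067). The median was -0.13 without both IL-4 replicate 1 and IL-4+CGRP replicate 2 and -0.12 with the gene length trend removed. The list passed without IL-4 replicate 2 or IL-4+CGRP replicate 3, and the mt-Co1 call ended in every leave-one-out fit except that without IL-4+CGRP replicate 2. It also ended with upper quartile factors, library totals alone, a mean count of at least 50, DESeq2, limma-voom and a dispersion fit that was not robust. Among transcripts without poly(A) tails, chosen after their values were seen, 5S ribosomal RNA genes summed to 9, 4 and 3 counts in the IL-4 libraries and 193, 333 and 1010 in the IL-4+CGRP libraries. Of these, n-R5s121, n-R5s124 and n-R5s103 were called higher (adjusted p = 0.0019, adjusted p = 0.0037 and adjusted p = 0.028); the n-R5s103 call ended without IL-4 replicate 1, 2 or 3 or IL-4+CGRP replicate 1, and with the length trend removed. Rpph1 (the RNA of RNase P) had 0, 2 and 2 counts against 47, 58 and 277 (adjusted p = 0.15), and Rn7sk 41, 41 and 26 against 169, 213 and 777 (adjusted p = 0.21). Neither passed the edgeR test, nor did Rn7s1, Rn7s2 (both adjusted p = 0.15) and Rmrp (adjusted p = 0.086), with log2 fold changes of 5.12, 5.12 and 6.31. For the 5S sum, Rpph1, Rn7sk, Rn7s1 and Rn7s2, every IL-4+CGRP library lay above every IL-4 library. Genes with a count numbered 18283 to 18809 in IL-4 and 18958 to 19313 in IL-4+CGRP libraries. A difference in library preparation between the groups was not tested and cannot be told apart from CGRP, which limits all 511 calls.

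Annotation terms in the deposited table were tested among called genes. Of 2845 terms, 35 were over-represented among higher and 38 among lower genes by a one-sided Fisher's exact test. Terms share genes, so these are not separate findings. Asthma, allograft rejection and phagosome, for example, all held H2-Aa, H2-Ab1, H2-DMa, H2-DMb1 and H2-Eb1 among lower genes. Antigen processing and presentation led the lower terms, with 16 of 56 genes (adjusted p = 1.1e-10), including H2-Aa, Cd74, Ciita and Calr. Cellular response to lipopolysaccharide (17 of 108 genes, adjusted p = 1.1e-06; Arg1, Cd14 and Il1rn among them) and inflammatory response (20 of 159 genes, adjusted p = 1.3e-06; Ccr1 and Ccr7 among them) led the higher terms. Cell surface tied with inflammatory response (30 of 351 genes, Fisher's exact test adjusted p = 1.3e-06). It was also over-represented among lower genes (27 of 351, Fisher's exact test adjusted p = 2.9e-08) and did not pass camera (adjusted p = 0.94). Extracellular matrix (12 of 88 genes, adjusted p = 5.3e-04), with Thbs1, Mmp8 and Timp1, and T cell costimulation (6 of 20 genes, adjusted p = 0.0015), with Cd28, Cd80, Cd86 and Pdcd1lg2, were also over-represented among higher genes. The Ccr7 call ended without IL-4 replicate 2, the Cd28 call without IL-4 replicate 2 or IL-4+CGRP replicate 1, the Timp1 and Pdcd1lg2 calls without IL-4 replicate 1, 2 or 3, and the Cd80 call in every leave-one-out fit except that without IL-4+CGRP replicate 2. Among genes changed at least 2-fold, 0 terms passed by Fisher's exact test in either direction, against 116 higher and 69 lower at an unadjusted p under 0.05. By camera, antigen processing and presentation (adjusted p = 6.2e-04) and extracellular matrix (adjusted p = 0.0052) passed, while cellular response to lipopolysaccharide (adjusted p = 0.63), inflammatory response (adjusted p = 0.21) and T cell costimulation (adjusted p = 0.19) did not. Over all terms camera called 26 higher and 67 lower, and 0 with an estimated correlation. There the adjusted p = 0.99 for cell surface and adjusted p = 0.98 for the other terms named here.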

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

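The fits without the correlated pair of libraries, without mitochondrial and ribosomal RNA genes and with the gene length trend removed were chosen only after the result was seen. Of the 511 calls, 0 changed direction in any of the 18 alternatives in which they were tested. This adds little, because their groups did not overlap and the other scalings shifted values only slightly, so reversals were hardly possible. In every leave-one-out fit, 182 of them were called. DESeq2 called 460 genes (418 shared with the edgeR calls), limma-voom 430 (423 shared) and a dispersion fit that was not robust 429 (419 shared). Of 118 named genes called, 65 were called in every alternative; Il4ra, Arg1, Thbs1, Inhba, Itgax, H2-Aa and Lpl were among them. Across 142 named genes, 261 values lost the threshold (53 genes) and 27 gained it (7 genes). The median log2 fold change of all genes lay between -0.005 and 0.023 under the other scalings. Low counts limit genes such as Cxcl3 and Il6, and a 1.3-fold change was recovered in only 32% of simulated genes.

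With no count filter, 584 genes were higher and 434 lower (118 and 42 by at least 2-fold), over more genes tested. With a mean count of at least 50, 20 higher and 10 lower genes changed at least 2-fold, over fewer genes. Leaving out a library gave 140 to 915 higher and 80 to 950 lower genes, and 31 to 83 and 12 to 34 by at least 2-fold; the highest higher and lower counts came without IL-4+CGRP replicate 2. Without both IL-4 replicate 1 and IL-4+CGRP replicate 2, 1066 genes were higher and 1187 lower (102 and 44 by at least 2-fold). With the gene length trend removed, 471 were higher and 389 lower. The cause of these increases was not tested apart from the length trend.

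With the replicate number as a block, 176 genes were higher and 86 lower. Same-numbered libraries did not deviate together (correlations of -0.19, -0.18 and 0.13), so the numbers were not taken as pairs, and the fit has fewer degrees of freedom. These are correlations of each library's deviations from its group mean across genes. The highest such value between libraries of different groups was 0.29, for IL-4 replicate 1 and IL-4+CGRP replicate 2. Lists past the threshold fell from 9 higher and 14 lower to 0 and 0 with an estimated correlation, and ranged from 6 to 9 and 13 to 14 over the leave-one-out fits. Annotation terms fell from 35 higher and 38 lower to 0 and 0 with genes of at least 2-fold, and camera called 67 lower; the cause was not tested.

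Reversed values were all of genes that did not pass. Retnla went from 0.03 to -0.17 without IL-4 replicate 2 and -0.25 without IL-4+CGRP replicate 2. Il10 went from -0.043 to 0.093 without IL-4 replicate 1 and 0.004 without IL-4+CGRP replicate 3 (leave-one-out range -0.132 to 0.093), 0.013 without the correlated pair and 0.022 with the length trend removed. The cause was not tested.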

Other observations

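The tests of mt-Co2, of MHC class II, of Il4ra and, for the ribosomal lists, of library variation and of lower expression were chosen only after the result was seen, and so was the length trend fit, whose bounds were written after the lists were seen but before that fit was run; the splits were not. The genes in this paragraph were chosen after their values were seen. Genes of calcium-dependent phospholipid binding were over-represented among lower genes, with 5 of 24 (one-sided Fisher's exact test, adjusted p = 0.0059), all annexins, Anxa1 to Anxa5; by camera the set did not pass (adjusted p = 0.80). Anxa3 fell from 128 ± 4.08 to 100.4 ± 2.34 CPM (SD, n = 3; edgeR adjusted p = 0.0028). Anxa6 rose, from 223 ± 3.57 to 262 ± 0.956 CPM (SD, n = 3; edgeR adjusted p = 0.012). The Anxa2 and Anxa6 calls ended in every leave-one-out fit except that without IL-4+CGRP replicate 2, the Anxa5 call without IL-4 replicate 1, 2 or 3 or IL-4+CGRP replicate 3, and the Anxa4 call without IL-4 replicate 3. Of 10 genes of chemorepellent activity 4 were higher (one-sided Fisher's exact test, adjusted p = 0.0089; camera adjusted p = 0.012), Nrg1, Sema4a, Sema7a and Flrt3. The Sema7a and Flrt3 calls ended without IL-4 replicate 1 or 2 or IL-4+CGRP replicate 3, and also without IL-4 replicate 3 for Sema7a and IL-4+CGRP replicate 1 for Flrt3. Collagen catabolic process had 5 of 16 genes higher, Mmp8, Mmp13, Mmp14, Mmp25 and Mmp27 (one-sided Fisher's exact test, adjusted p = 0.0053), but did not pass camera (adjusted p = 0.13), and Mmp27 rose from 51.6 ± 2.78 to 72.6 ± 1.27 CPM (SD, n = 3; edgeR adjusted p = 5.4e-04). The Mmp13 call ended without IL-4 replicate 2. Each of these 3 terms had an adjusted p = 0.98 by camera with an estimated correlation.

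With more Il4ra, a uniformly larger IL-4 response could be the cause. Against this, 7 of the 35 tested members of the IL-4 induced list were lower past the threshold, Clec7a and Mmp12 among them, while 8 were higher. Higher Il4ra with part of the IL-4 induced genes stays a hypothesis, found and tested in the same 6 libraries and without a group that lacked IL-4.

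MHC class II genes and Itgax were lower in IL-4+CGRP. The median of 7 class II genes (classical genes, DM genes and Cd74) lay between -0.50 and -0.48 under the other scalings. These scalings moved the median of all genes only between -0.005 and 0.023, so they could not have changed the class II median much. A larger error of scaling was not tested. Fewer dendritic-like cells stay open. The dendritic cell list shares Batf3, Cd209a, Ccl22 and Irf4 with the IL-4 induced list, so it is a poor gauge of such cells. The other 14 tested dendritic cell markers had a median of -0.09 against -0.50 for the class II genes. The 95% bootstrap interval of the difference was 0.044 to 0.708, with a lower bound of 0.03 in a second set of draws. The bootstrap resampled genes, which are not independent, so the interval does not measure the spread between libraries. Its lower bound was -0.006 without IL-4 replicate 2 and -0.015 without IL-4+CGRP replicate 2, where the markers' median was -0.20. Lower Ciita stays open as well. Ciita, the class II transactivator, fell from 101 ± 2.68 to 75.6 ± 2.38 CPM (SD, n = 3, log2 fold change -0.42, edgeR adjusted p = 8.4e-04). Of the 17 MHC class I genes in the list, which do not need it, 0 were called. Outside the list, the class I gene H2-M2 was called lower with all libraries. Without IL-4+CGRP replicate 2, though, 8 class I genes were called lower and the class I list passed as lower (median -0.098), so a fall limited to class II was not established.

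The ribosomal protein and oxidative phosphorylation lists were lower, with medians of -0.25 and -0.16. The ribosomal protein share varied in a way that did not follow the groups. In 1 IL-4+CGRP library, replicate 2, it was 1.71%, above the 1.51% of the lowest IL-4 library. Leaving this library out made both medians lower, so it cannot account for them. IL-4 replicate 1 had the highest share, 1.85%, and both medians were smaller in size without it. Variation in that library may account for part of the lower medians. Short genes of about 600 bases deviated by 0.27 (log2) in IL-4 replicate 1 and 0.24 in IL-4+CGRP replicate 2, and by -0.21 and -0.22 in IL-4+CGRP replicates 1 and 3. With each library's length trend removed the medians were -0.14 and -0.07, and both lists passed camera (adjusted p = 3.6e-07 and adjusted p = 9.5e-04) but not with an estimated correlation (adjusted p = 0.37 and adjusted p = 0.53). A length trend as the whole cause and lower expression with CGRP therefore cannot be told apart with 3 libraries a group; the ribosomal median ranged from -0.46 without IL-4+CGRP replicate 2 to -0.13 without IL-4 replicate 1, and the oxidative phosphorylation median from -0.31 to -0.07 without the same libraries.

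Counts of mt-Co2 at 0 in the IL-4 libraries may come from reads shared with its nuclear copy Gm28661, identical over 681 of 684 bases. Another mitochondrial gene with such a copy, mt-Co3, had 0, 2 and 644 counts in the IL-4+CGRP libraries, at least 215-fold apart against a floor of 3 counts per library. Summed with its copies, mt-Co2 measured 393 ± 52 CPM in IL-4 and 307 ± 45 in IL-4+CGRP (SD, n = 3). The other 11 tested mitochondrial genes did not rise with CGRP as a set, with a median log2 fold change of -0.26. Levels of those with copies are uncertain, such as mt-Atp6 with 1646, 355 and 176 counts in the IL-4 libraries. The list of 12, with mt-Co2, did not pass camera (adjusted p = 0.067), and its median was -0.12 with the gene length trend removed. Higher mitochondrial transcription is therefore argued against only weakly.

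The real grouping called 511 genes and 23 lists. Among the 10 splits of the 6 libraries into groups of 3, 1 split, the real one, gave as many genes and 1 as many lists; the highest of the others gave 5 genes and 5 lists. With 10 splits no share under 0.05 can be reached.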
